A study of Phrynocephalus vlangalii with 2 samples.

How the data were processed

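Per the labels, total RNA of liver, lung, heart and muscle of adult lizards was extracted with the Promega SV kit and pooled by population, and standard Illumina libraries were made, 1 each for Madoi and Maqu. Per the series' design text, the authors used Trinity, BLAST and KaKs_Calculator. The aligner, the counting tool, all versions and the test behind the p-values are not given in the sources used here.

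The single deposited table lists 58458 assembled genes, with identifiers of the form that Trinity gives. The expected counts deposited by the authors are estimated reads per assembled gene and population, with decimals, and their sums are 63636521 for Madoi and 66401051 for Maqu. The RPKM values of the authors equal the count divided by the effective length and by about the library total, as found from the values. The log2 fold change deposited by the authors is the log2 of Madoi RPKM over Maqu RPKM. The authors' p-values and FDR compare 2 single libraries and are quoted only as the authors' deposited table. The smallest sum over both libraries was 6.89 reads. Columns of other samples numbered 0.

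Expected counts were rounded to whole numbers. Library sizes were scaled by TMM (edgeR 4.0.16 in R), with factors of 0.983 for Madoi and 1.02 for Maqu. Log2 ratios of Madoi over Maqu used a pseudocount of 0.5 reads scaled by library size. An assembled gene was called higher or lower when it had at least 10 reads in both libraries together, differed at least 2-fold, and had an exact 95% counting interval (Clopper-Pearson, from the binomial share of reads in Madoi) excluding 1. The depth allows a limit of 3 counts for a gene at 0, or 0.0479 CPM in Madoi and 0.0444 CPM in Maqu, and a fold against 0 was computed against these 3 counts per library. Reads are not independent molecules, and intervals and limits cover counting error only. No test across genes was made, because with 1 library per population there is no spread between replicates.

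The annotation text of the file was taken as the gene name, and reads of assembled genes with the same text were summed. Copies of one name share this sum, and close paralogs with one name cannot be told from each other. The protein accessions in the table were not turned into names. Gene lists were fixed before the data were examined, as were the samples, the alternatives and the rule for named genes. They are 36 lists: liver enzymes, liver secreted proteins, fast skeletal muscle, heart, slow muscle or ventricle, lung epithelium, airway cilia, erythroid, leukocyte, yolk and oestrogen, fat, pancreas and gut, hypoxia sensing, targets of hypoxia-inducible factors, oxygen transport, glycolysis, gluconeogenesis and glycogen, citric acid cycle, nuclear and mitochondrial oxidative phosphorylation, fatty acid oxidation, lipid synthesis, antioxidant, heat shock, DNA repair, extracellular matrix, vessels, complement, interferon, antigen presentation, cell cycle, circadian, immediate early, iron, cytosolic ribosome and proteasome. Their 537 symbols were matched by hand to annotation texts after the file was opened, and 393 had one; texts that cover a broader family were left out where the family goes beyond the marker. A list's value is its median log2 ratio over names with at least 10 reads, with the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

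The named genes are the 10 highest and 10 lowest ratios among names with at least 10 reads in each library and 100 together, the 3 with most reads in each direction among names with 0 reads in the other library and at least 50 in one, the 2 highest and 2 lowest of each list with at least 50 reads, and the names of hypoxia-inducible factors 1 and 2 alpha, prolyl hydroxylase, vascular endothelial growth factor, erythropoietin receptor, globins and lactate dehydrogenase. Names saying uncharacterized, hypothetical or unknown, or of transposable elements, were left out. No annotation text for globins was used here, and 1 gene that the rule selects is not reported here.

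The other settings tried were scaling by library total, size factors by the median of ratios (DESeq2 1.42.0; 0.960 for Madoi and 1.04 for Maqu), no filter, a filter of 50 reads, a 4-fold threshold, no counting interval, the copy with the highest mean in place of the sum, and a pseudocount of 5 reads. Leaving out assembled genes with 0 reads in one library or a log2 ratio beyond 5 in either direction, and setting genes at 0 to their limit, were added after the data were seen. Calculations used Python with numpy, pandas and scipy. The calls were tested on simulated data with 200 genes changed among 58458 in the Madoi against Maqu comparison: 94.0% of the 100 genes changed 3-fold and 100% of those changed 8-fold were recovered, and 0.904% of the unchanged genes were called. The simulated counts were Poisson draws around the mean of the 2 libraries, with no spread between animals or pools. The shares therefore cover counting error only and are no error rate for the calls in the real libraries. Of 40 simulated random lists of unchanged genes, 0 lay outside the middle 95% of their matched lists.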

Results

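The question, as far as the series title gives it, was how a cold-blooded vertebrate lives at high altitude, approached by comparing populations of one lizard species. RNA was sequenced from adults of the toad-headed lizard Phrynocephalus vlangalii of 2 populations, Madoi and Maqu, with 1 library per population. Each library was a pool of liver, lung, heart and muscle RNA. The deposited table held 58458 assembled genes, with 63636521 estimated reads in the Madoi library and 66401051 in the Maqu library. An annotation text was given for 14472 of the assembled genes, under 4819 names. Values below are log2 ratios of Madoi over Maqu. Among names with at least 1000 reads in each library the 95% counting interval was at most 0.25 wide on the log2 scale. These intervals cover counting error only. With 1 library per population no difference has a replicate check, and each ratio compares these 2 libraries, not the populations.

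The medians of the liver, complement and lung epithelium lists lay below 0, and those of the lipid synthesis and antioxidant lists above 0. The binomial interval of the median spanned 0 for lipid synthesis (-0.42 to 1.30), antioxidant (-0.07 to 0.91) and secreted liver proteins (-0.73 to 1.23). It lay below 0 for liver enzymes (-0.88 to -0.28) and complement (-1.20 to -0.53). The antioxidant enzyme NAD(P)H dehydrogenase (quinone) and the heat shock 70kDa protein 1/8 were higher in Madoi. Carboxypeptidase A1 and carboxypeptidase B, digestive enzymes of the pancreas, had far fewer reads in Madoi. A large set of assembled genes was read almost only in Madoi. Of 58439 assembled genes with at least 10 reads, 16648 were at least 2-fold higher in Madoi with a counting interval excluding 1, 6270 were lower, and 35521 were neither. Of those higher in Madoi, 10925 had 0 reads in Maqu or a log2 ratio of at least 5, and these Madoi-only genes held 8.14% of the Madoi reads. The opposite class, Maqu-only, held 389 assembled genes and 0.169% of the Maqu reads. Outside both classes, 5723 assembled genes were higher in Madoi and 5881 lower, so that the share of higher calls was 49.3% there against 72.6% over all. Percentiles below compare with random lists that include copies of both classes, except where values without those copies are given. For lists whose median did not depend on such copies, this mostly lowered the percentile.

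**Figure D1:**
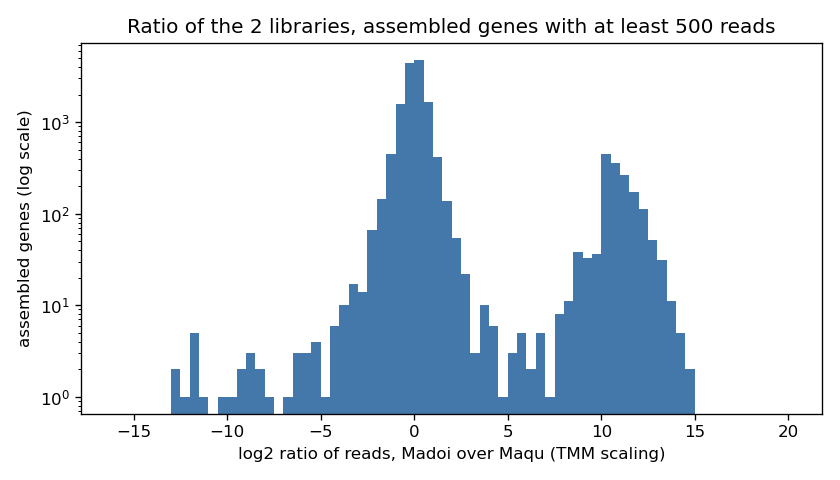
Histogram of the log2 ratio of reads, Madoi over Maqu after TMM scaling (horizontal axis), against the number of assembled genes on a log scale (vertical axis), for assembled genes with at least 500 reads in both libraries together. Most lie around 0, 20 lie between 3 and 5, and 1596 lie at 5 or above, against 30 at -5 or below.

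Cytosolic ribosomal proteins had a median of 0.83 over 78 names, above all 10000 random lists matched on mean expression (percentile 100), with 28 higher and 0 lower. In 76 of these names a Madoi-only copy was added to the sum, and without Madoi-only and Maqu-only copies the median was 0.34 over 76 names (percentile 100), with 1 higher. Proteasome subunits, which form the main protein-degrading complex of the cell, had a median of 0.60 over 24 names (percentile 100), and -0.08 without those copies (percentile 13.8). Large subunit ribosomal protein L13Ae had 10238 reads in Madoi and 3 in Maqu, a log2 ratio of 11.62 with a counting interval from 10.30 to 14.12. 20S proteasome subunit alpha 2 had 2300 reads in Madoi and 0 in Maqu, 827-fold higher against the limit of 3 counts, with a counting interval from 672-fold upward. Both names had a Madoi-only copy and no other. Such copies may come from another organism, so a difference in the lizard genes cannot be read from these 2 ratios. Cell cycle genes had a median of 1.03 over 14 names, with 7 higher, and 0.07 without those copies, with 0 higher. Cyclin B stood at 3.47 and at 0.26 without its Madoi-only copies, and polo-like kinase 1 at 3.30 and 0.39.

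The liver lists had medians below 0, with few names past the 2-fold threshold. The liver enzymes had a median of -0.68 over 12 names (percentile 0), with 0 higher and 2 lower, and the secreted liver proteins -0.57 over 9 names (percentile 0.09), with 2 higher and 0 lower. The tyrosine-degrading enzyme 4-hydroxyphenylpyruvate dioxygenase was 5.22-fold lower in Madoi, with 5575 reads against 31436, and tryptophan 2,3-dioxygenase had a ratio of -1.07. The clotting proteins fibrinogen alpha chain and fibrinogen beta chain stood at -0.87 and -0.73. In the other direction, glycine N-methyltransferase had a ratio of 0.50 and apolipoprotein A-I, a carrier of plasma lipid, 1.23. Antithrombin III stood at 0.03, and at -0.68 without its Madoi-only copies. Complement and acute phase genes, also products of the liver for the most part, had a median of -1.02 over 13 names (percentile 0), with 7 lower and 0 higher. Mannose-binding lectin was 3.96-fold lower and complement factor H 3.53-fold lower in Madoi, and complement component 7 stood at 0.39.

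**Figure D2:**
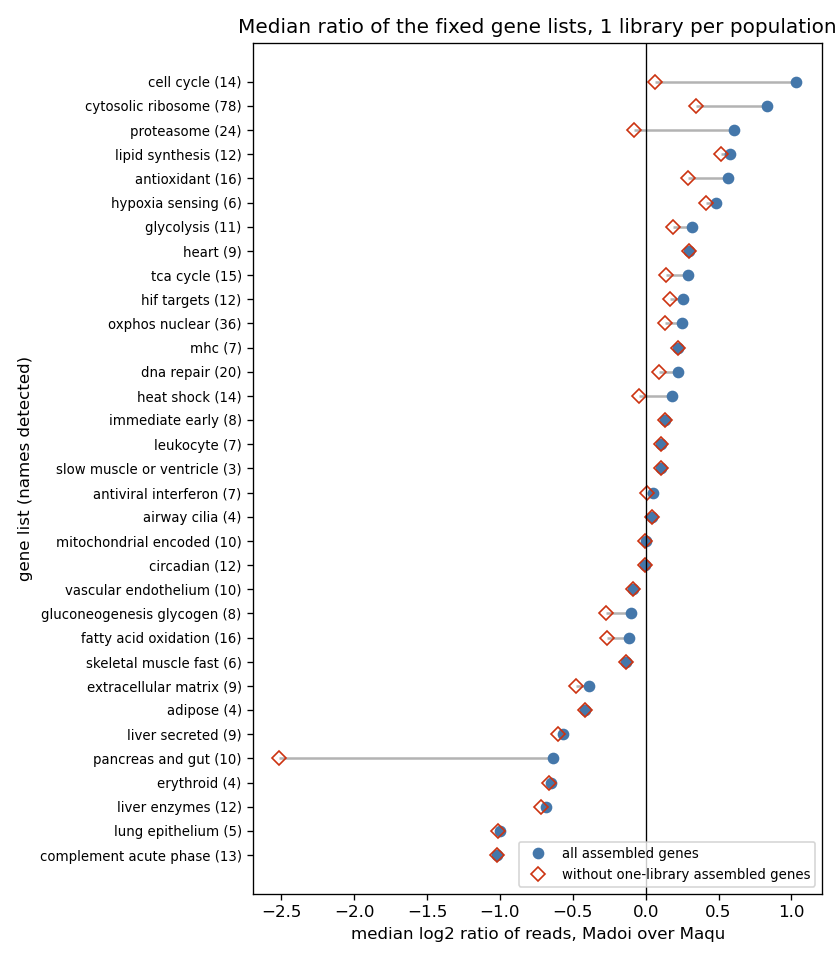
Median log2 ratio of reads, Madoi over Maqu (horizontal axis), for each gene list with at least 3 detected names (vertical axis, number of names in brackets). Filled circles use all assembled genes and open diamonds leave out Madoi-only and Maqu-only ones; complement and acute phase genes lie lowest among the circles at -1.02, pancreas and gut lowest among the diamonds at -2.52, and cell cycle genes move from 1.03 to 0.07.

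The markers of the other pooled tissues went different ways. Lung epithelium had a median of -0.998 over 5 names (percentile 0.015), with 0 higher and 2 lower. Within it, homeobox protein Nkx-2.1 stood at -1.38 and surfactant protein A, which coats the air spaces, at -1.12, and lysosomal-associated membrane protein 3 had nearly equal reads in both libraries, 8763 and 9462. Heart genes had a median of 0.30 over 9 names (percentile 76.6), with 2 higher and 0 lower. These were the heart-forming transcription factors T-box protein 5 at 1.23 and homeobox protein Nkx-2.5 at 1.13, while phospholamban stood at -0.42 and natriuretic peptide A at -0.09. Fast skeletal muscle genes had a median of -0.14 over 6 names (percentile 5.86), from 0.41 for skeletal troponin C to -0.23 for ryanodine receptor 1. The 3 slow muscle or ventricle troponins had a median of 0.10 (percentile 40.9), with troponin C of slow skeletal and cardiac muscles at 0.36. Airway cilia genes had a median of 0.04 over 4 names (percentile 43.7).

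Of the markers of other cells in these tissues, the B cell gene CD79B antigen was higher and 0 erythroid, fat cell or leukocyte names were lower by the 2-fold threshold. Erythroid genes had a median of -0.65 over 4 names (percentile 0.36), among them 5-aminolevulinate synthase, the first enzyme of haem synthesis, at -0.73 and the anion exchanger of solute carrier family 4 at -0.56. Fat cell genes had a median of -0.42 over 4 names (percentile 1.65), with lipoprotein lipase at -0.80 and adiponectin at -0.03. Leukocyte genes had a median of 0.10 over 7 names (percentile 45.5), with CD79B antigen at 1.30 and macrophage colony-stimulating factor 1 receptor at -0.61. The only detected name of the yolk and oestrogen list, nuclear receptor subfamily 3 group A member 1, stood at 0.38 (percentile 68.0), and ferritin heavy chain, the only name of the iron list, at 0.13 (percentile 39.1).

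The pancreas and gut list had a median of -0.64 over 10 names (percentile 0), with 5 lower and 3 higher. Without Madoi-only and Maqu-only copies the median was -2.52 over 8 names (percentile 0), with 6 lower and 0 higher, and with the highest copy of each name -2.099. Carboxypeptidase A1 had 8 reads in Madoi and 7651 in Maqu, a ratio of -9.71 with a counting interval from -11.00 to -8.81, and carboxypeptidase B stood at -4.82. Triacylglycerol lipase at 4.38 and chymotrypsin at 1.65 were higher in Madoi as sums over copies, and stood at -0.13 and -4.58 without Madoi-only and Maqu-only copies.

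Hypoxia-inducible factor 2 alpha, a transcription factor that is stabilised at low oxygen, had a ratio of 0.52 with 62108 reads in Madoi and 46856 in Maqu, and hypoxia-inducible factor prolyl hydroxylase, which marks these factors for degradation, 0.64. The von Hippel-Lindau protein stood at -1.14 and hypoxia-inducible factor 3 alpha at -0.56. Hypoxia-inducible factor 1 alpha had 363 reads in Madoi and 0 in Maqu, and both assembled genes with that name were Madoi-only. It was 131-fold higher against the limit of 3 counts, with a counting interval from 106-fold upward. Madoi-only copies may come from another organism, so a difference in the lizard gene cannot be read from this. The list had a median of 0.48 over 6 names (percentile 88.7), and 0.41 over 5 names without Madoi-only and Maqu-only copies (percentile 97.0). Targets of these factors had a median of 0.26 over 12 names (percentile 74.0), with 1 higher and 0 lower. The higher one was the glucose transporter of solute carrier family 2, member 1, at 1.14, followed by pyruvate dehydrogenase kinase isoform 1 at 0.76, and the lower end was heme oxygenase at -0.47 and endothelin at -0.43, which stood at -1.47 and -1.08 with their highest copy. Vascular endothelial growth factor A/B and placental growth factor, under one name in the file, stood at 0.36. The erythropoietin receptor, the only detected name of the oxygen transport list, stood at -0.56 (percentile 7.41).

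Glycolysis, the breakdown of glucose, had a median of 0.32 over 11 names (percentile 74.0), with L-lactate dehydrogenase at 0.59 and pyruvate kinase at 1.86, the latter at -0.27 without its Madoi-only copy. Glycogen and gluconeogenesis genes had a median of -0.10 over 8 names (percentile 7.09), with phosphoenolpyruvate carboxykinase, the enzyme that commits carbon to glucose synthesis, at -0.99. The 1,4-alpha-glucan branching enzyme had 853 reads in Madoi and 0 in Maqu, all in Madoi-only copies. It was 307-fold higher against the limit of 3 counts, with a counting interval from 249-fold upward. The citric acid cycle had a median of 0.29 over 15 names (percentile 77.7), nuclear genes of oxidative phosphorylation 0.25 over 36 names (percentile 82.3) and 0.14 without Madoi-only and Maqu-only copies, and mitochondrially encoded genes 0.00 over 10 names (percentile 6.62), from 0.69 for NADH dehydrogenase I subunit 5 to -0.42 for cytochrome b. Citrate synthase had 2300 reads in Madoi and 0 in Maqu, again from a Madoi-only copy. Fatty acid oxidation had a median of -0.11 over 16 names (percentile 2.01), with 2 lower. These were carnitine O-palmitoyltransferase 1, which lets fatty acids into mitochondria, at -1.83 (-2.91 with its highest copy), and the coactivator PPAR gamma coactivator 1 alpha at -1.66.

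Lipid synthesis genes had a median of 0.58 over 12 names (percentile 98.9), 4 higher and 1 lower. Stearoyl-CoA desaturase, which makes monounsaturated fatty acids, was 8.50-fold higher as a sum over copies, and had a ratio of 2.16 without its Madoi-only copies. Fatty acid synthase stood at 1.10 and squalene monooxygenase, an enzyme of cholesterol synthesis, at 1.30, and hydroxymethylglutaryl-CoA synthase at -1.35. The elongase named elongation of very long chain fatty acids protein 6 had 143 reads in Madoi and 0 in Maqu, at least 51.4-fold higher, all in a Madoi-only copy.

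Antioxidant genes had a median of 0.57 over 16 names (percentile 99.9), with 3 higher and 0 lower, and 0.29 without Madoi-only and Maqu-only copies (percentile 98.8), with 1 higher. NAD(P)H dehydrogenase (quinone) was 5.06-fold higher, with 18123 reads against 3864. Thioredoxin 1 stood at 1.55, and at -0.10 without its Madoi-only copies, and glutathione peroxidase at -0.17. Heat shock genes had a median of 0.18 over 14 names (percentile 50.1), with 1 higher and 0 lower. The median turned to -0.049 with the highest copy of each name, and to the same value without Madoi-only and Maqu-only copies (percentile 17.1). The higher name was heat shock 70kDa protein 1/8, a chaperone, 2.98-fold higher with 100005 reads in Madoi, and heat shock protein 110kDa stood at -0.93. DNA repair genes had a median of 0.22 over 20 names (percentile 77.4), with xeroderma pigmentosum group C-complementing protein at -0.67.

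Extracellular matrix genes had a median of -0.39 over 9 names (percentile 0.28), with 0 higher and 2 lower. These were lumican at -1.28 and decorin at -1.25, both proteoglycans that bind collagen fibres. Vascular endothelium had a median of -0.09 over 10 names (percentile 12.1), from 0.51 for angiopoietin 1, which turned to -0.28 with its highest copy, to -0.74 for von Willebrand factor. Interferon response genes had a median of 0.05 over 7 names (percentile 35.9), with interferon regulatory factor 1 at 0.99 and signal transducer and activator of transcription 2 at -0.57, and antigen presentation genes 0.22 over 7 names (percentile 61.8), with the peptide transporter of ABC subfamily B, member 3, at 0.69. Immediate early genes had a median of 0.13 over 8 names (percentile 50.5), with c-fos at -1.94 and activating transcription factor 3 at 0.84.

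Circadian clock genes lay on both sides. Their median was -0.01 over 12 names (percentile 27.6), with 3 higher and 2 lower. Aryl hydrocarbon receptor nuclear translocator-like protein 1 stood at -2.62 and its partner, the circadian locomoter output cycles kaput protein, at -1.29, the activating arm of the clock. Cryptochrome, a repressor, stood at 1.52 and class B basic helix-loop-helix protein 2 at 1.12.

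Over all 4451 names with at least 10 reads in each library and 100 in both together, the highest ratios were those of synaptic vesicle glycoprotein 2 at 7.87, lysosomal Pro-X carboxypeptidase at 6.44 and the AC39 subunit of the V-type proton pump at 6.41. Without their Madoi-only copies these 3 stood at 3.29, 0.05 and 2.67. Nucleophosmin 3 stood at 5.78, SOX group B transcription factors at 5.01, retinol dehydrogenase 12 at 4.70, membrane metallo-endopeptidase-like 1 at 4.62 and twist at 4.43, each with a Madoi-only copy. Without those copies they stood at 1.31, 2.105, 1.82, -1.12 and 0.50. The gamma 2 subunit of the GABA A receptor at 4.80 and sialyltransferase 7B at 4.75 had no such copy. The lowest ratios were those of ABC transporter subfamily C, member 6, at -5.46, prostaglandin-H2 D-isomerase at -5.19, chymotrypsin C at -5.10 and carboxypeptidase B at -4.82. The first had 3 of 3 copies in the Maqu-only class and prostaglandin-H2 D-isomerase 1 of 1, and chymotrypsin C stood at -0.23 without its Maqu-only copy. Deoxyribonuclease-1 stood at -3.95, transmembrane protease, serine 13, at -3.38, aquaporin TIP at -3.25 and purinergic receptor P2X 5 at -3.11. Whether each of these names, aquaporin TIP among them, is a lizard gene was not tested. Names of photosynthesis were lower in Madoi as well, with a median of -2.57. Cystinyl aminopeptidase was 12.2-fold lower in Madoi, with 16979 reads against 222738, and glycine dehydrogenase subunit 2 was 9.22-fold lower. Among 105 names with at least 50 reads in Madoi and 0 in Maqu, prostasin had the most at 8527 reads, followed by chitin deacetylase with 3335 and a non-specific protein-tyrosine kinase with 2845. Prostasin was 3068-fold higher against the limit of 3 counts, with a counting interval from 2494-fold upward. All copies of these 3 names were Madoi-only, so a difference in lizard genes cannot be read from them. The opposite case, at least 50 reads in Maqu and 0 in Madoi, was met by 0 names.

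In the authors' deposited table, a total of 6098 assembled genes were marked significant, 5397 higher and 701 lower in Madoi. The marked genes of the authors' deposited table were those with a p-value under 0.05 and an absolute log2 fold change of at least 1, since 6098 met both, and their FDR reached 0.441. With an FDR of at most 0.05 instead, the authors' deposited table gave 1395. Of the 5397 marked higher in the authors' deposited table, 5070 were Madoi-only, and 4582 had an infinite fold change.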

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

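The alternative that leaves out Madoi-only and Maqu-only genes was chosen after the data were seen. Without them, 5723 assembled genes were higher in Madoi in place of 16648. A filter of 50 reads gave 10938 higher and 3815 lower, and a 4-fold threshold 12917 higher and 2200 lower. These drops follow from the construction: fewer genes enter without those classes or with the filter of 50 reads, and the 4-fold threshold is stricter on the same genes. Scaling by library total gave 16276 higher and 6725 lower, and median-of-ratios factors 16686 and 6203. The proteasome median turned from 0.60 to -0.016 with the highest copy and to -0.077 without Madoi-only and Maqu-only genes. Cell cycle moved to 0.071 and 0.066, the cytosolic ribosome to 0.36 and 0.34, and nuclear oxidative phosphorylation to 0.14 under both. Iron, a list of 1 name, moved from 0.13 to 0.079 by library total and 0.28 with the highest copy. Slow muscle or ventricle moved to 0.054 by library total. All other list medians stayed within the interval over their members, or for a list of 1 name within its counting interval, under each setting tried. The 2 moves by library total follow from the construction, since that scaling lowers the ratios of genes read in both libraries by nearly the same amount. Some of these intervals were so wide that staying within them shows little. The pancreas and gut interval ran from -4.82 to 1.65, while its median moved from -0.64 to -2.52 without the classes. That of glycogen and gluconeogenesis ran from -0.99 to 10.79. Medians near 0 that changed sign within these intervals were heat shock (-0.049 with the highest copy and without the classes), airway cilia (-0.0060 by library total, -0.029 with the highest copy), interferon response (-0.0017 by library total), leukocyte (-0.065 with the filter of 50 reads), mitochondrially encoded (-0.048 by library total, -0.0059 with the highest copy and without the classes) and circadian clock (0.0016 by median-of-ratios factors, 0.095 with the highest copy, 0.023 with the filter of 50 reads). Of all names called higher or lower, 85 turned sign without Madoi-only and Maqu-only copies, among them trypsin (-2.57), chymotrypsin (-4.58), membrane metallo-endopeptidase-like 1 (-1.12), pyruvate kinase (-0.27), thioredoxin 1 (-0.10), triacylglycerol lipase (-0.13) and the gamma subunit of F-type ATPase (-0.060, also with the highest copy). With the highest copy, angiopoietin 1 turned to -0.28, and carnitine O-palmitoyltransferase 1 (-2.91), heme oxygenase (-1.47) and endothelin (-1.08) were lower still. Where that copy was Madoi-only the ratio was far higher, as for cyclin B (13.29), chymotrypsin (12.49), triacylglycerol lipase (12.21), polo-like kinase 1 (10.96) and thioredoxin 1 (9.77). Setting genes at 0 to their limit left all 36 medians within these intervals. Percentiles also depended on the classes, whose copies enter the random lists. Lists whose median was the same without the classes had higher percentiles there, except complement, which stayed at 0. Circadian clock rose from 27.55 to 52.065 and leukocyte from 45.49 to 68.15. Heart rose from 76.63 to 94.96 and vascular endothelium from 12.11 to 25.31. The percentile of the mitochondrially encoded list rose too. No replicate could be left out, since each population has 1 library, and depth limits ratios of genes below 50 reads.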

Other observations

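The tests of the Madoi-only genes, of the exocrine pancreas and intestinal names and of an equal shift of liver genes were chosen after those results or part of them had been seen.

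Outside the Madoi-only and Maqu-only classes, the highest ratios were those of the gamma 2 subunit of the GABA A receptor at 4.80, sialyltransferase 7B at 4.75, neurofilament light polypeptide at 3.80 and synaptic vesicle glycoprotein 2 at 3.29. These names were chosen by the same rule after the classes were left out. Names of photosynthesis were also present. Of 17 such names, 16 were at least 2-fold lower in Madoi, with a median of -2.57, and the ribulose-bisphosphate carboxylase small chain had 41531 reads in Madoi and 59234 in Maqu. These reads, present in both libraries, may come from another organism than the lizard, which was not tested. Of the 17 names, 0 had a Madoi-only copy, so leaving out that class does not remove them. Of 18 names that the file's own text ties to invertebrates, insect hormones, chitin or trehalose, 18 had a Madoi-only copy and 15 had no other copy. Chitin deacetylase had 3335 reads in Madoi and juvenile hormone epoxide hydrolase 1779, both with 0 in Maqu.

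The Madoi-only assembled genes held 8.14% of the Madoi reads. Splitting of lizard transcripts between populations by the assembly was argued against only for annotated names with at least 50 reads in copies shared by both libraries. In 664 of these, Madoi-only copies held at least 20% of the name's Madoi reads. The median of their shared copies differed by 0.048 (resampling interval -0.01 to 0.09) from that of names with no Madoi-only copy. The shared copies were thus not lower in Madoi, where splitting would give -0.67. Madoi-only genes with no annotation or no shared copy are not covered, and 29.4% of the Madoi-only genes were annotated. Of the ribosome and proteasome names, 94.1% had both a Madoi-only copy and a copy read in both libraries. This cannot decide on lizard genes silent in Maqu. Every cell uses ribosomes and proteasomes, so a copy read in both libraries was near certain for these names. Names with no shared copy, such as the 105 with 0 reads in Maqu, are not covered by it. RNA of another organism in the Madoi pool, such as prey or a parasite, may be the source: 98.0% of the 102 ribosome and proteasome names had a Madoi-only copy, against 2.33% of 43 names of the blood, vessel, complement and heart lists and 28.4% of 74 names of the other tissue and cell marker lists, pancreas and gut, liver and extracellular matrix among them. Which organism it is was not tested.

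Of 12 exocrine pancreas names, 8 of which are in the pancreas and gut list, 66.7% were at least 4-fold lower in Madoi with all copies summed, among them carboxypeptidase A1 with 8 reads against 7651, while trypsin stood at 1.52, chymotrypsin at 1.65, triacylglycerol lipase at 4.38 and pancreatic elastase I at -0.04. Without Madoi-only and Maqu-only copies, 6 of the 8 names left were at least 4-fold lower, and chymotrypsin C at -0.23 and triacylglycerol lipase at -0.13 were not. Carboxypeptidase A1, pancreatic elastase I, pancreatic elastase II (3 reads against 1435) and pancreatic endopeptidase E (5 against 2682) dropped out there. Trypsin kept only 14 reads in Madoi and 92 in Maqu, of 36815 and 13882. Leaving out both classes thus also removed Maqu reads of these enzymes. Values without the Madoi-only copies alone were not computed. Pancreas carried along with a dissected organ into the Maqu pool stays open, since Madoi-only copies of 5 of the names may come from another organism and add to the sums. Trypsin, chymotrypsin and triacylglycerol lipase were higher in Madoi only through such copies. Without both classes they stood at -2.57, -4.58 and -0.13. Chymotrypsin C had no Madoi-only copy and stood at -5.10 with its Maqu-only copy. Intestine stays open too, since its 2 names had a median of -0.64, with intestinal fatty acid-binding protein at -1.19 and villin 1 at -0.08. A difference between the populations in digestive enzymes was not tested and remains open with 1 library each.

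The liver lists had medians of -0.68 and -0.57, and of -0.72 and -0.60 without Madoi-only and Maqu-only copies. Also without those copies, 17 further liver-made proteins outside the fixed lists, picked by name before their values were seen, had a median of -0.78 (binomial interval -1.14 to -0.26). A smaller share of liver RNA in the Madoi pool may account for this shift. Whether all liver genes shifted equally stays open: without those copies, 68.4% of 38 liver names lay within 0.5 of their common median of -0.66, against a median of 76.3% in random lists matched on mean expression (percentile 14.1), with coagulation factor XIII B polypeptide at -2.28 and apolipoprotein A-I at 1.23. A difference between populations within the liver remains open and untested.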
